A study of Mus musculus with 36 samples.

How the data were processed

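Small RNA was sequenced from liver and epididymal white adipose tissue (eWAT) of C57BL/6 male mice of the F1 generation at 24 weeks of age. Each tissue held 3 diet groups, named LF, HF and HFLF, with 6 libraries each, 36 libraries in all. Per the labels' protocols, RNA was extracted with TRI reagent, and 1 ug of total RNA entered the NEXTFLEX Small RNA-seq v3 kit with unique dual indexes. The mice ate chow to 6 weeks of age and a specific diet for the next 18 weeks. The treatment protocol of every sample gives the same diet, LFD, while the diet tags of the groups are LFD, HFD and HFLFD. The labels therefore do not say whether a group name stands for the diet of the mouse itself or of its father, and the groups are called by their names only. Table columns name a tissue by L or W, a group by C, H or R, and a number. L and W were read as liver and eWAT from the tables deposited per tissue, and C, H and R as LF, HF and HFLF from the abbreviations alone. Nothing beyond the sample titles says that replicates are separate mice, or that the same number in both tissues is the same mouse, so p-values measure the spread between these samples.

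Per the submitters' processing notes, reads were trimmed with cutadapt and aligned with Bowtie to GRCm38.p6. Versions, alignment settings, the treatment of the random bases of the adapters and the release of the miRNA annotation are not given in the sources used here. The authors deposited read counts per mature miRNA and precursor in 2118 lines that name 1966 mature miRNAs and 1226 precursors. A mature miRNA with several precursors has several lines, and for 51 of 87 such miRNAs these were identical. The column totals therefore hold reads more than once. Counts outside the highest line of each miRNA made up 13.7% to 26.7% of a column, and where lines differ not all of them need be repeats. The deposited CPM columns are the counts scaled to that column total. The authors' log2 tables hold log2 CPM for 171 miRNAs in 16 liver libraries and 180 miRNAs in 18 eWAT libraries. Library sizes recomputed with TMM over all 36 libraries on the summed lines matched those behind the log2 values within 0.0442% in liver and 0.0494% in eWAT. Replicate 4 of LF and replicate 6 of HF are missing from the authors' liver log2 table and present in the count table. The source of that choice is not given in the sources used here.

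For each mature miRNA the line with the highest count was used, since 51 of the 87 miRNAs with several lines had identical lines. Where the lines differed, reads found only in the lines not used may be left out. On that basis the totals ran from 7866583 to 18832842 counts per library. The counts behind a share of a single library were large, and the widest 95% Wilson interval for a let-7 share was 0.0594 percentage points. Intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules. Between replicates of a group the lowest chi-square per degree of freedom was 72.1, far above what counting error gives.

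Counts were tested in R 4.3.3 with edgeR 4.0.16. Factors were TMM, miRNAs were kept by filterByExpr with its default minimum count of 10 and total of 15, and the robust quasi-likelihood F test was applied, with Benjamini-Hochberg adjusted p under 0.05 as the threshold and no threshold on fold. Each tissue was fitted with its 18 libraries in 3 groups. All 36 libraries in 6 groups were fitted for the difference between the tissues in LF and for the difference between the tissues in the effect of a diet group. CPM values scaled by TMM differ between the fit of 1 tissue and the fit of both. Fitted log2 fold changes are given with their standard error. They use edgeR's prior count, and the log2 CPM of the set tests used a prior count of 2. A miRNA at 0 in all libraries of a group is given no fitted fold of its own. Medians over the interaction calls do rest on such fits. The floor is the CPM of 3 counts over the summed totals of the group. The let-7 total is the summed CPM of the 5p arms of let-7a to let-7i and miR-98, compared as log2 by a 2-sided exact permutation test. It took all 924 assignments of 6 against 6, whose smallest possible p is 0.0021645, and was adjusted over the 6 comparisons.

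Sets were tested with camera in limma 3.58.1 at the preset correlation of 0.01 between miRNAs, adjusted over the sets of a comparison, and again with an estimated correlation. The fry test of limma was run beside camera and adjusted in the same way. It is given here only for the call that held with an estimated correlation. A set with fewer than 3 measured members got no set test. There were 23 lists. They covered let-7 5p arms, let-7 3p arms, hepatocyte, adipocyte, macrophage and granulocyte, lymphocyte, erythroid, endothelial, fibroblast with stellate and smooth muscle, striated muscle, the epithelial miR-200 family, germ cell and epididymis, pancreas and endocrine, neural, and miRNAs linked to obese liver or adipose tissue. The others were the miR-29 family, the miR-34 and miR-449 family, miR-17-92 with its paralogous clusters, the miR-15 and miR-16 family, the miR-183-96-182 cluster, the Dlk1-Dio3 imprinted cluster, the Sfmbt2 cluster of miR-466, miR-467, miR-297 and miR-669, and mirtrons with others outside Drosha processing. Cell type lists hold miRNAs enriched in a cell type and not specific to it, and several miRNAs, such as miR-143, miR-155 and miR-21a, stand in more than 1 list. The germ cell list shares miR-34b, miR-34c and miR-449 with the miR-34 and miR-449 list, and the list linked to obesity shares miR-200a, miR-200b and miR-429 with the miR-200 list. Counts of members past the threshold are given over all miRNAs tested and adjusted over the list alone.

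The design, the lists, the alternatives and the rule for which miRNAs the text names were fixed before the data were examined. Within a tissue the rule takes up to 10 rises and 10 falls with the largest fold among called miRNAs of at least 10 CPM and, where fewer than 10 are called, those with the smallest p up to 10, as values. It adds every let-7 5p arm, up to 4 members of each list, the 10 most abundant miRNAs of each tissue and, for the tissue difference, the 10 called miRNAs with the smallest p. The alternatives were DESeq2 1.42.0, limma trend, size factors by relative log expression (RLE) or plain CPM in place of TMM, no filter, and a filter of 10 CPM in at least 6 libraries. Others were the most abundant miRNA left out, summed lines, 2 groups per fit, pseudocounts of 1, 0.5 and 5 on the deposited CPM, the replicate number as a block, and each library left out in turn within its tissue. Fits without 4 libraries that stood apart, each library left out of the fits over both tissues, and limma on the deposited log2 tables were added after the data were seen.

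The count test was checked on simulated data made from the means, dispersions and library sizes of the 18 libraries of each tissue. In each of 5 draws 200 miRNAs were changed in HF. With so many changed the adjusted threshold is easier to pass than with few, so the shares below do not hold for sparse changes. In liver, over 478 miRNAs, the test recovered 20.8% of changes of 1.5-fold, 41.3% of 2-fold and 68.3% of 4-fold, and 89.5% of the 2-fold changes among miRNAs of at least 100 CPM. In eWAT, over 638 miRNAs, it recovered 19.0%, 46.0% and 71.9%, and 82.1% of the 2-fold changes among miRNAs of at least 100 CPM. False calls were 1.98% of calls in liver and 2.99% in eWAT. Each miRNA was drawn on its own, without libraries in which many miRNAs shift together, as some did here. These rates may therefore not carry over to the real libraries.

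Positions are those of the precursor genes in the GENCODE M21 annotation of GRCm38, matched by name, which gave 1142 of the 1226 precursors a position. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Reads were not used here, so isoforms, read lengths and other small RNA classes are not analysed here.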

Results

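MicroRNAs (miRNAs) were counted in 18 liver and 18 eWAT libraries from F1 male mice, with 6 libraries in each of the groups LF, HF and HFLF. The title of the series names let-7 in the passing of metabolic decline from fathers to offspring, so the let-7 family is given in every comparison. The total counts of LF replicates 1 to 6 in liver were 13304011, 8525421, 7866583, 8496919, 13024929 and 15608292. Those of HF were 13870427, 12788313, 14559181, 14809508, 15662851 and 18832842, and those of HFLF 10642336, 9198584, 11469460, 13563025, 12727089 and 18152684. In eWAT the LF libraries held 17371055, 13898442, 11512416, 9619779, 12619038 and 15090599 counts. The HF libraries held 14803991, 9584187, 11935885, 9066683, 10793565 and 13959338, and the HFLF libraries 16846318, 13103448, 14664364, 17714156, 13710769 and 15902083.

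Liver counts were dominated by miR-122-5p, the hepatocyte miRNA that supports cholesterol and lipid metabolism, which made up 45.6% to 57.0% of the counts of a library and averaged 513288 CPM. It was followed by let-7f-5p at 65779 CPM, miR-21a-5p at 61438, let-7a-5p at 43554, let-7g-5p at 32294, let-7c-5p at 25949, miR-26a-5p at 25884, miR-30a-5p at 24695, miR-192-5p at 19028 and miR-30d-5p at 14058. In eWAT the most abundant was miR-143-3p, a miRNA of adipocytes and smooth muscle, with 12.8% to 22.8% of the counts and a mean of 168814 CPM. Next came let-7f-5p at 81586 CPM, miR-26a-5p at 78982, let-7c-5p at 56262, miR-21a-5p at 56033, let-7a-5p at 53837, miR-30a-5p at 48751, let-7g-5p at 34889, miR-10b-5p at 34412 and miR-30d-5p at 25217. The 10 most abundant miRNAs held 78.2% to 89.0% of liver counts and 61.3% to 66.3% of eWAT counts. The number of miRNAs with a count was 699 to 849 in eWAT and 540 to 633 in 16 of the liver libraries. Liver LF replicate 4 held 316 and liver HF replicate 6 held 368.

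On GRCm38 miR-122-5p comes from chromosome 18, 65248861 to 65248926, in an exon of the lincRNA AC157910.3, and miR-143-3p from chromosome 18, 61649196 to 61649258, outside any annotated host. The mature let-7a-5p is shared by precursors that include Mirlet7a-1 on chromosome 13, 48538179 to 48538272, in an exon of the lincRNA 6720427I07Rik, and Mirlet7a-2 on chromosome 9, 41536716 to 41536811. For let-7f-5p they are Mirlet7f-1 on chromosome 13, 48537829 to 48537917, and Mirlet7f-2 on chromosome X, 151912346 to 151912428, in an intron of Huwe1. Reads of the mature arms cannot be assigned to 1 of these loci, and let-7 members that differ by a base may share reads.

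The let-7 family, which restrains growth and insulin signalling, had a summed 5p level in liver of 210558 ± 85818 CPM in LF, 193585 ± 74769 in HF and 164186 ± 24836 in HFLF (mean ± SD, n = 6). In eWAT the sums were 272378 ± 20067 CPM in LF, 281383 ± 22516 in HF and 274701 ± 31240.2 in HFLF. On the log2 scale the liver total differed by -0.11 ± 0.27 (difference ± SE) between HF and LF (exact permutation p = 0.574). It differed by -0.30 ± 0.22 between HFLF and LF (exact permutation p = 0.201) and by -0.18 ± 0.21 between HFLF and HF (exact permutation p = 0.489). The eWAT differences were 0.05 ± 0.06 for HF against LF (exact permutation p = 0.502), and 0.01 ± 0.08 for HFLF against LF (exact permutation p = 0.920), where plain CPM gave -0.03. For HFLF against HF the difference was -0.04 ± 0.08 (exact permutation p = 0.641). The eWAT difference between HF and LF turned to -0.03 without LF replicate 6 and -0.02 without HF replicate 6. That between HFLF and LF turned negative without any 1 LF library or HFLF 3, 4, 5 or 6, to -0.08 without LF replicate 6. Adjusted over the 6 comparisons the permutation p was 0.769 for all but the HFLF and LF comparison of eWAT, at 0.920. None of these differences exceeded the spread between libraries. A pair of liver libraries stood above the rest, LF replicate 4, with let-7 at 26.6% of its counts (95% Wilson interval 26.6069% to 26.6664%), and HF replicate 6, at 25.9% (25.8692% to 25.9087%). The other 16 liver libraries held 15.98% to 18.5%. Without LF replicate 4 the log2 difference between HF and LF was 0.05, without HF replicate 6 it was -0.28, and without both it was -0.11. The difference between HFLF and LF was -0.12 without LF replicate 4, and that between HFLF and HF was -0.02 without HF replicate 6.

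**Figure D1:**
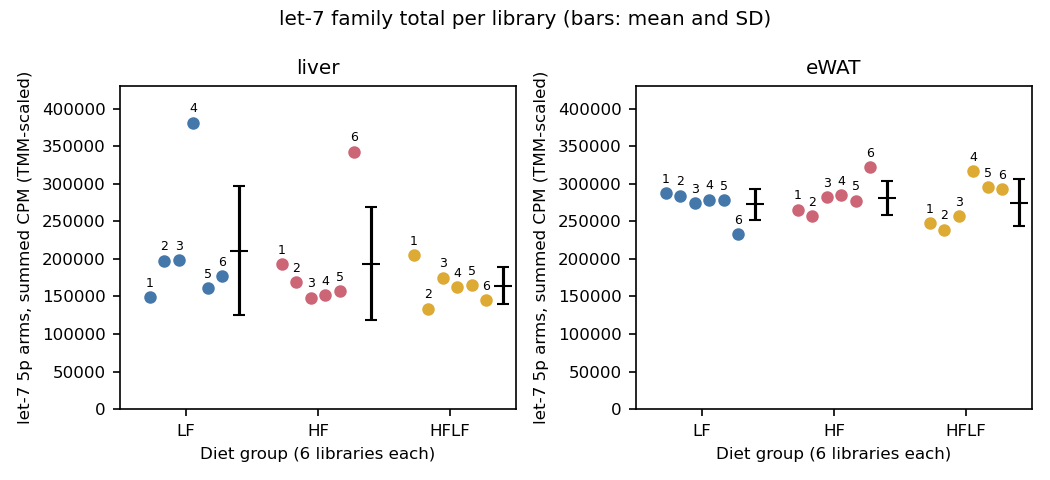
Summed CPM of the let-7 5p arms in each liver and eWAT library, with replicate numbers at the points and the mean and SD of each diet group of 6 libraries beside them. Liver LF replicate 4 (381183 CPM) and HF replicate 6 (342657 CPM) lie above all other liver libraries.

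**Figure D2:**
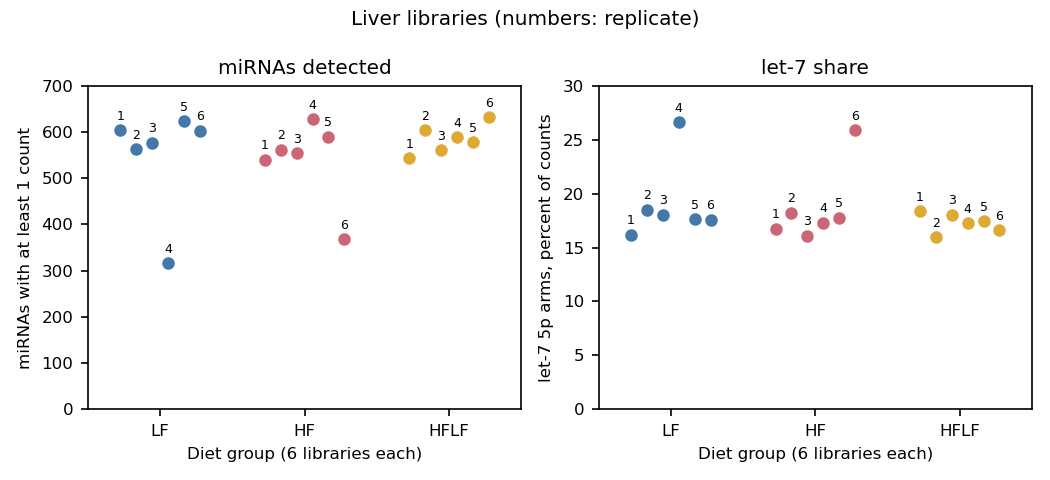
Number of miRNAs with at least 1 count and percent of counts in let-7 5p arms for each liver library by diet group, with replicate numbers at the points. Replicates LF 4 and HF 6 have 316 and 368 miRNAs, against 540 or more in the other 16, and the highest let-7 shares.

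In liver the comparison of HF with LF asked which miRNAs differ between these groups. No single miRNA passed the test. The hepatocyte list lay higher in HF as a set, with 11 of 12 members above 0 and a median log2 difference of 0.20 (camera adjusted p = 0.0126, and adjusted p = 0.261 with an estimated correlation). Its members included miR-802-5p, which is raised in obese liver, at 143 ± 55.7 CPM in LF and 230.1 ± 106 in HF (n = 6, log2 difference 0.69 ± 0.29). For miR-101b-3p the means were 7068 ± 1148 and 8586 ± 824 (0.28 ± 0.13), and miR-101a-3p differed by 0.30 ± 0.15. The dominant member miR-122-5p lay at -0.11 ± 0.17, and with it the summed list held 600834 ± 116114 CPM in LF and 565416 ± 115041 in HF. The maternally expressed Dlk1-Dio3 cluster lay lower as a set, with 3 of 21 members above 0 and a median of -0.94 (camera adjusted p = 0.00759, and adjusted p = 0.698 with an estimated correlation). Its most abundant members here were low, among them miR-379-5p at 19.7 ± 13.0 CPM in LF and 10.3 ± 4.54 in HF (-0.94 ± 0.46). The summed cluster held 95.4 ± 44.8 CPM in LF and 56.6 ± 14.8 in HF.

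The single liver miRNA with the smallest p was miR-378a-3p, which lies in an intron of Ppargc1b (chromosome 18, 61397835 to 61397900) and acts in mitochondrial metabolism. It measured 1820.4 ± 142 CPM in LF and 2249 ± 351 in HF (n = 6, log2 difference 0.30 ± 0.12). The related miR-378b and miR-378c differed by 0.50 ± 0.21 and 0.26, and miR-1247-5p, in an exon of Dio3os (chromosome 12, 110278048 to 110278129), by 1.62 ± 0.64 at 6.30 ± 5.17 CPM in LF and 19.6 ± 8.50 in HF. Lower values in HF were those of miR-32-3p (-0.77 ± 0.33, and -0.43 without LF replicate 4 and HF replicate 6). The let-7 5p arms differed by -0.09 ± 0.23 for let-7f, -0.18 ± 0.26 for let-7a, -0.04 ± 0.11 for let-7g, -0.16 ± 0.29 for let-7c, -0.15 ± 0.42 for let-7b and -0.41 ± 0.31 for let-7e. The list had 0 of 9 members above 0 and did not pass (camera adjusted p = 0.193).

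For these liver groups edgeR called 0 of 478 miRNAs, with a smallest adjusted p of 0.998. Under an unadjusted p of 0.05 were 16 miRNAs, where a share of 0.05 of those tested is 23.9. In simulated draws with no miRNA changed, 3.56% of miRNAs fell under that p. DESeq2 called 0, with 26 under an unadjusted p of 0.05, and limma 0, with 17. With all libraries no list member passed in a liver comparison when adjusted over the list alone, and without LF replicate 4 and HF replicate 6 a striated muscle and a Dlk1-Dio3 member did here. Without these libraries, left out after the data were seen, camera still called the hepatocyte (median 0.15) and Dlk1-Dio3 (-0.70) lists and also the let-7 5p list (-0.16, adjusted p = 0.0408). Each had an adjusted p = 0.656 with an estimated correlation. Without this pair edgeR called 0, with 30 under an unadjusted p of 0.05.

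Between HFLF and LF liver, the let-7 5p arms lay lower in HFLF as a set, with 0 of 9 members above 0 and a median log2 difference of -0.40 (camera adjusted p = 0.000856, and adjusted p = 0.460 with an estimated correlation). Under plain CPM the median was -0.19 with 2 of 9 above 0, in a comparison where the median of all miRNAs moved from 0.01 under TMM to 0.16. The members ran from let-7e-5p (chromosome 17, 17830352 to 17830444, in an intron of Spaca6), to let-7i at -0.06 ± 0.12. For let-7e the means were 1875 ± 800.3 CPM in LF and 1099 ± 312 in HFLF (-0.77 ± 0.31, n = 6). Between these lay let-7b at -0.64 ± 0.42, let-7c at -0.49 ± 0.30, let-7a at -0.45 ± 0.26, let-7d at -0.40 ± 0.26, let-7f at -0.35 ± 0.23 and let-7g at -0.07 ± 0.11. LF replicate 4, the library highest in let-7, is among those compared. Without it and HF replicate 6 let-7b-5p lay at -0.09, let-7c-5p at -0.15, let-7a-5p at -0.17 and let-7f-5p at -0.09. The germ cell and epididymis list also lay lower, with 1 of 13 members above 0 and a median of -0.85 (camera adjusted p = 0.00113). Of the 23 list calls made within the tissues, this was the 1 that held with an estimated correlation (adjusted p = 0.0480 with an estimated correlation). The fry test did not call this list (fry adjusted p = 0.237). Its members were rare in liver, with a sum of 41.1 ± 16.5 CPM in LF and 24.3 ± 6.77 in HFLF. They include miR-871-3p at 8.24 ± 4.72 and 4.04 ± 2.27 CPM (-1.02 ± 0.68), miR-465c-3p (-0.85 ± 0.57, and -0.50 without LF 4 and HF 6), miR-741-3p (-0.51 ± 0.71, and -0.08 without them) and miR-465c-5p (-0.24 ± 0.78). The paralogs miR-465a, miR-465b and miR-465c may share reads.

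The Dlk1-Dio3 cluster lay lower in HFLF liver too, with 2 of 21 members above 0 and a median of -0.82 (camera adjusted p = 0.000904, and adjusted p = 0.460 with an estimated correlation). Examples were miR-379-5p (-0.91 ± 0.47) and miR-541-5p (-0.58 ± 0.71). The hepatocyte list lay higher, with 10 of 12 members above 0 and a median of 0.30 (camera adjusted p = 0.0425, and adjusted p = 0.419 with an estimated correlation). It held miR-192-5p at 0.36 ± 0.28, miR-194-5p at 0.35 ± 0.18 and miR-148a-3p at 0.26 ± 0.26, while its dominant member miR-122-5p was at -0.24 ± 0.17. Without LF replicate 4 and HF replicate 6 these lay at 0.16, 0.22, 0.07 and -0.13. The erythroid list, which marks red cells, lay higher with 6 of 7 members above 0 and a median of 0.40 (camera adjusted p = 0.0425, and adjusted p = 0.460 with an estimated correlation). Its members include miR-451a at 0.32 ± 0.22, miR-486b-5p at 0.44 ± 0.21 and miR-144-5p at 0.40 ± 0.35. The single miRNA with the smallest p was miR-1247-5p, with 20.4 ± 12.03 CPM in HFLF (1.68 ± 0.64). Next were miR-574-5p at 188 ± 153 CPM in LF and 101 ± 22.9 in HFLF (-0.89 ± 0.35), and miR-2137 (-1.58 ± 0.63). Without LF replicate 4 and HF replicate 6 miR-574-5p lay at -0.33 and miR-2137 at -0.93. They were followed by miR-103-3p, a regulator of insulin sensitivity, at 2220.3 ± 157 and 2646 ± 239 (0.25 ± 0.11), the muscle miRNA miR-1a-3p (-0.91 ± 0.39), miR-101b-3p (0.29 ± 0.13) and miR-30e-3p (0.50 ± 0.23).

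For HFLF against LF liver edgeR called 0 of 478, with 14 under an unadjusted p of 0.05 and a smallest adjusted p of 0.989. DESeq2 called 0, with 21 under an unadjusted p of 0.05, and limma 0, with 18. Without LF replicate 4 and HF replicate 6 the erythroid list was no longer called by camera, with a median of 0.30 and 6 of 7 members above 0, and the let-7 (median -0.15), hepatocyte (0.19), germ cell (-0.58) and Dlk1-Dio3 (-0.84) lists were. All 4 calls were lost with an estimated correlation (adjusted p = 0.768, adjusted p = 0.370, adjusted p = 0.305 and adjusted p = 0.305 with an estimated correlation).

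Between HFLF and HF liver, the miR-29 family, which restrains collagen synthesis, lay lower in HFLF as a set, with 0 of 7 members above 0 and a median log2 difference of -0.49 (camera adjusted p = 0.0246, and adjusted p = 0.556 with an estimated correlation). Its values include miR-29c-3p at 378 ± 448 CPM in HF and 222 ± 41.8 in HFLF (-0.77 ± 0.50, n = 6), miR-29b-3p at -0.49 ± 0.33 and miR-29a-3p at -0.15 ± 0.21. The Sfmbt2 cluster lay lower as well, with 4 of 21 members above 0 and a median of -0.98 (camera adjusted p = 0.0387, and adjusted p = 0.556 with an estimated correlation). Examples were miR-669c-5p at -0.24 ± 0.50 and miR-466i-5p at -0.45 ± 0.73. HF replicate 6 held 12993.5 CPM of the miR-29 family, against 5626 to 6281 in the other HF livers, and 131 CPM of the Sfmbt2 cluster, against 22.4 to 41.8. Without that library and LF replicate 4 neither list was called, the medians being -0.02 and -0.28, and miR-29c-3p, miR-29b-3p and miR-29a-3p lay at 0.18, 0.08 and 0.07. Single miRNAs with the smallest p were miR-378b at 26.7 ± 4.12 CPM in HF and 18.0 ± 1.94 in HFLF (-0.57 ± 0.21), miR-378d (-0.54 ± 0.26) and miR-190a-5p (-1.10). The leukocyte miRNAs miR-155-5p (-0.68 ± 0.37), miR-223-3p (-0.82 ± 0.45) and miR-142a-3p (-0.88 ± 0.48) came next. Without the same pair of libraries these lay at -0.20, -0.02 and 0.04, miR-378d at -0.20 and miR-190a-5p at 0.14. The let-7 arms lay at -0.26 for let-7f, -0.27 for let-7a, -0.04 for let-7g and 0.04 for let-7i, and their list did not pass (camera adjusted p = 0.0935). By edgeR 0 of 478 were called, with 5 under an unadjusted p of 0.05. DESeq2 called 0, with 8 under that p, and limma 0, with 11.

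In eWAT the comparison of HF with LF was led by the miR-200 family, which marks epithelial cells. The means of miR-200c-3p (chromosome 6, 124718322 to 124718390, in an intron of the antisense gene Gm15884) were 2445 ± 4542 CPM in LF and 21.3 ± 8.20 in HF (n = 6). Those of miR-200b-3p were 2602 ± 4018 and 65.7 ± 14.4. In LF the family was high in a pair of libraries, replicate 1 with 16656 CPM and replicate 4 with 21371 CPM, against 59.5 to 290.3 in the other 16 eWAT libraries. The list had 0 of 7 members above 0 and a median log2 difference of -5.26 (camera adjusted p = 7.21e-05, and adjusted p = 0.446 with an estimated correlation). The miR-183-96-182 cluster, also epithelial and sensory, had 0 of 3 members above 0 and a median of -4.03 (camera adjusted p = 0.00478, and adjusted p = 0.446 with an estimated correlation). Its sum was 602 and 3352 CPM in the same pair of libraries and at most 83.6 in the other 16.

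The germ cell and epididymis list lay lower in HF eWAT, with 0 of 22 members above 0 and a median of -1.14 (camera adjusted p = 7.21e-05, and adjusted p = 0.547 with an estimated correlation). It included miR-34c-5p at 476 ± 1031 CPM in LF and 39.5 ± 37.6 in HF (-3.59 ± 1.15, n = 6). The sum of the list ran from 49.3 to 4615 CPM over the LF libraries, with the highest value in replicate 1. The pancreas and endocrine list had 0 of 6 members above 0 and a median of -0.56 (camera adjusted p = 0.0143, and adjusted p = 0.446 with an estimated correlation). It was led by miR-375-3p (chromosome 1, 74900658 to 74900721), a miRNA of endocrine and epithelial cells, at 617 ± 1382 CPM in LF and 13.5 ± 14.2 in HF (-5.51 ± 1.59). The list summed to 3878 CPM in LF replicate 1 and 316 to 748 in the other LF libraries, and miR-375-3p lay at -2.02 without that library, where miR-34c-5p lay at -0.54. The Sfmbt2 cluster had 6 of 29 members above 0 and a median of -0.44 (camera adjusted p = 0.0318, and adjusted p = 0.593 with an estimated correlation). Here miR-669c-5p was at -0.67 ± 0.37 and miR-467e-5p at -0.75 ± 0.26. In the other direction, 49 of 64 Dlk1-Dio3 members lay above 0 with a median of 0.15 (camera adjusted p = 0.00155, and adjusted p = 0.547 with an estimated correlation). Examples were miR-379-5p at 0.12 ± 0.16 and miR-127-3p at 0.17 ± 0.15.

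Of single miRNAs in HF against LF eWAT the smallest p values belonged to miR-200c-3p (-6.84 ± 1.60), miR-200b-3p (-5.31 ± 1.28), miR-200a-3p (-5.26 ± 1.28), miR-141-3p (-7.67 ± 1.88) and miR-429-3p (-5.23 ± 1.31). They were followed by miR-182-5p (-4.03 ± 1.07), miR-205-5p, a miRNA of squamous and glandular epithelium (-5.99 ± 1.65), miR-183-5p (-3.97 ± 1.11), miR-204-5p (-1.60 ± 0.46) and miR-375-3p. Without LF replicates 1 and 4 miR-200c-3p lay at -0.54, miR-200b-3p at -0.27, miR-182-5p at -0.31, miR-205-5p at -0.17 and miR-204-5p at -0.29. Of the abundant miRNAs of the adipocyte list miR-143-3p lay at 0.03 ± 0.16 and miR-30a-5p at 0.03 ± 0.11, and the list did not pass (17 of 31 above 0, median 0.01, camera adjusted p = 0.865). The let-7 5p arms lay at 0.06 ± 0.08 for let-7f, -0.01 ± 0.11 for let-7c, 0.08 ± 0.09 for let-7a, -0.01 ± 0.08 for let-7g, 0.12 ± 0.12 for let-7b, 0.02 ± 0.08 for let-7i and 0.08 ± 0.10 for let-7d. The lists of let-7 3p arms (10 of 11 above 0, median 0.09, adjusted p = 0.105), lymphocyte (5 of 13, -0.03, 0.495), fibroblast (4 of 14, -0.14, 0.153) and striated muscle (0 of 5, -0.50, 0.153) did not pass camera. Nor did, in the same order of values, the lists of neural (2 of 5, -0.09, 0.536), obesity-linked (16 of 52, -0.08, 0.255), miR-34 and miR-449 (1 of 6, -3.50, 0.106), miR-17-92 (5 of 19, -0.08, 0.105) and mirtron miRNAs (7 of 10, 0.15, 0.145). Here the test pointed up for the lymphocyte list against its negative median, the mean of the adipocyte list was negative at -0.23, and that of the macrophage list positive at 0.05 against a median of -0.12. Such differences in sign also occurred among lists not called in the other comparisons, and not among the 23 called.

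**Figure D3:**
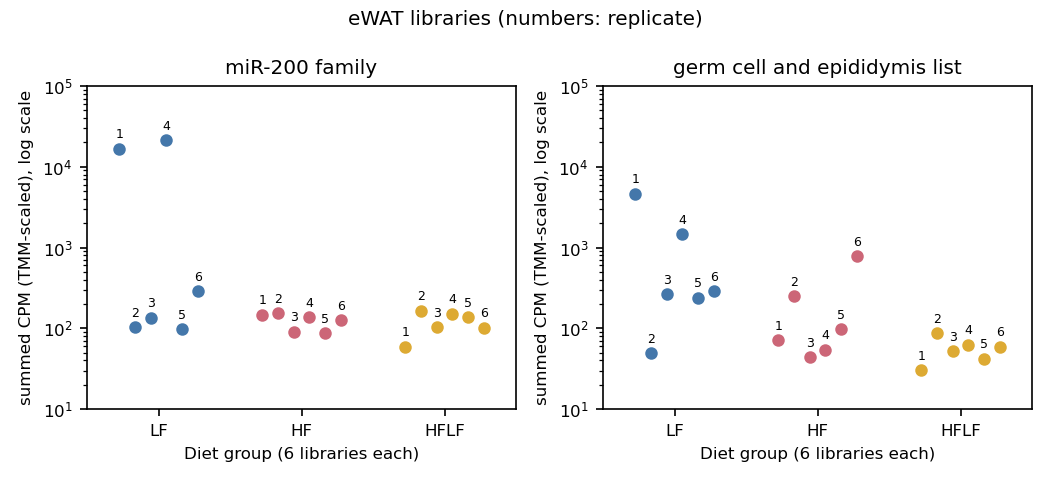
Summed CPM on a log scale of the miR-200 family and of the germ cell and epididymis list in each eWAT library by diet group, with replicate numbers at the points. LF replicates 1 and 4 hold 16656 and 21371 CPM of the miR-200 family, against at most 290.3 in the other 16 libraries.

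For HF against LF eWAT edgeR called 0 of 638 miRNAs, with a smallest adjusted p of 0.147. Under an unadjusted p of 0.05 were 49 (40 lower and 9 higher in HF), where a share of 0.05 of those tested is 31.9. In simulated draws with no miRNA changed, 3.88% of miRNAs fell under that p. DESeq2 called 16, all lower in HF and led by the miR-200 family and miR-182-5p, with 42 under an unadjusted p of 0.05, and limma called 0, with 34. Adjusted over the list alone, 7 of 7 miR-200 members, 3 of 3 of the miR-183 cluster, 4 of 6 of miR-34 and miR-449 and 3 of 52 obesity-linked miRNAs (miR-200a, miR-200b and miR-429) passed. So did miR-375-3p of the pancreas list, and let-7e-3p (0.45 ± 0.15) and let-7f-1-3p (0.70 ± 0.22) of the 3p arms. Without LF replicates 1 and 4, left out after the data were seen, edgeR called 0, with 13 under an unadjusted p of 0.05. Members of miR-34 and miR-449 summed to 4748 CPM in LF replicate 1 and 248 to 471 in the other LF libraries. Without the pair no member of any of these lists passed over the list alone. The miR-200, miR-183 and Sfmbt2 lists were then no longer called by camera (medians -0.36, -0.31 and 0.12), while the germ cell, pancreas and Dlk1-Dio3 lists were (adjusted p = 0.895, adjusted p = 0.571 and adjusted p = 0.846 with an estimated correlation). Their medians were 0.03, -0.73 and 0.20, and the germ cell list, still called as lower, had 13 of 22 members above 0.

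HFLF against LF eWAT gave the most miRNAs under an unadjusted p of 0.05, 74 lower and 24 higher in HFLF. The germ cell and epididymis list had 0 of 22 members above 0 and a median log2 difference of -4.46 (camera adjusted p = 6.72e-14, and adjusted p = 0.4001 with an estimated correlation). Its sum was 1154 ± 1770.2 CPM in LF and 55.5 ± 19.6 in HFLF (n = 6), with miR-34c-5p at -4.29 ± 1.19 and miR-465c-5p at -4.48 ± 1.45. LF replicate 1 held 4615 CPM of the list, against 49.3 to 1462 in the other LF libraries. The miR-200 family had 0 of 7 members above 0 and a median of -5.24 (camera adjusted p = 0.00072, and adjusted p = 0.495 with an estimated correlation), again against LF replicates 1 and 4. The miR-183 cluster had 0 of 3 and -4.61 (camera adjusted p = 0.0152, and adjusted p = 0.495 with an estimated correlation). The pancreas list had 0 of 6 and -1.17 (camera adjusted p = 0.0149, and adjusted p = 0.4001 with an estimated correlation). The Sfmbt2 cluster had 3 of 29 and -0.69 (camera adjusted p = 0.00072, and adjusted p = 0.495 with an estimated correlation). The miR-15 and miR-16 family lay higher, with 9 of 13 and 0.24 (camera adjusted p = 0.0299, and adjusted p = 0.495 with an estimated correlation). It held miR-195a-5p at 0.32 ± 0.11, miR-322-3p at 0.47 ± 0.17 and miR-16-5p at 0.13 ± 0.10. Plain CPM ended that call (camera adjusted p = 0.0632).

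The endothelial miRNAs miR-126a-3p, at 14766 ± 4813 CPM in LF and 19709 ± 2366 in HFLF (0.42 ± 0.16, n = 6), and miR-126a-5p (0.44 ± 0.14) formed a list too short for a set test. Its median was 0.43, and both passed when adjusted over the list alone. Single miRNAs with the smallest p were miR-200c-3p (-7.24 ± 1.63), miR-130b-5p (-0.97 ± 0.24), miR-182-5p (-4.61 ± 1.10), miR-429-3p (-5.54 ± 1.33), and miR-200b-3p (-5.24 ± 1.28). Next were miR-200a-3p (-5.21 ± 1.28), miR-375-3p (-6.68 ± 1.68), miR-141-3p (-6.97 ± 1.79), miR-200b-5p (-4.74 ± 1.23) and miR-34b-3p (-4.43 ± 1.16). Unlike the rest, miR-130b-5p had narrow spreads, with 20.97 ± 6.48 CPM in LF, 17.9 ± 3.73 in HF and 10.7 ± 2.67 in HFLF. The let-7 5p arms lay at 0.08 for let-7f, -0.06 for let-7c, 0.00 for let-7a, -0.02 for let-7g and 0.03 for let-7b. Adjusted over the list alone, 22 of 22 germ cell, 7 of 7 miR-200, 3 of 3 miR-183 and 6 of 6 miR-34 and miR-449 members passed, the last with miR-34a-5p higher (0.44 ± 0.16). So did 6 of 52 obesity-linked miRNAs, including miR-27a-3p (0.33 ± 0.10), and miR-7a-5p (-0.37 ± 0.14), miR-375-3p and miR-211-5p. The miR-34 and miR-449 sum was 4748 CPM in LF replicate 1 and 248 to 471 in the other LF libraries, and without that library miR-34c-5p lay at -1.25 and miR-34b-3p at -1.92. Without LF replicates 1 and 4 the 1 list member to pass over its list alone was of the miR-183 cluster. There miR-200c-3p lay at -0.95, miR-375-3p at -2.21, miR-130b-5p at -0.88, miR-126a-3p at 0.16 and miR-126a-5p at 0.23.

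For HFLF against LF eWAT edgeR called 0 of 638, with 98 under an unadjusted p of 0.05 and a smallest adjusted p of 0.0873. DESeq2 called 31, all lower in HFLF, with 95 under an unadjusted p of 0.05, and limma called 0, with 89. With a filter of 10 CPM in at least 6 libraries edgeR called 7 of 337, all lower, namely miR-130b-5p, miR-182-5p, miR-200a-3p, miR-200b-3p, miR-200c-3p, miR-429-3p and miR-375-3p. Leaving out LF replicate 2 gave 12 calls, LF replicate 5 gave 15 and LF replicate 6 gave 17, of which 5 were higher in HFLF (miR-708-3p, miR-126a-5p, miR-126a-3p, miR-22-3p and miR-27a-3p). Without LF replicates 1 and 4 there were 0, with 46 under an unadjusted p of 0.05. The germ cell (median -3.44) and pancreas (-1.34) lists were then still called by camera (adjusted p = 0.368 with an estimated correlation for each), and the miR-200 (-0.32), miR-183 (-0.91), Sfmbt2 (-0.06) and miR-15 and miR-16 (0.04) lists were not. The fibroblast list was called as higher (camera adjusted p = 0.0112, and adjusted p = 0.404 with an estimated correlation).

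Between HFLF and HF eWAT the germ cell list lay lower in HFLF, with 0 of 22 members above 0 and a median log2 difference of -3.23 (camera adjusted p = 8.68e-09, and adjusted p = 0.755 with an estimated correlation). The sum of the list was 215.6 ± 284 CPM in HF, from 44.1 to 775 with the highest in replicate 6, and 55.5 ± 19.6 in HFLF (n = 6). Among its members miR-465c-3p measured 12.2 ± 20.1 and 0.633 ± 0.718 CPM (-4.25 ± 1.46). The macrophage and granulocyte list also lay lower, with 2 of 13 above 0 and a median of -0.19 (camera adjusted p = 0.0286, and adjusted p = 0.755 with an estimated correlation). Its member miR-146b-5p (chromosome 19, 46342762 to 46342870, in an intron of Mfsd13a), which is induced in inflammation and in adipogenesis, had the smallest p of all. It measured 3062 ± 962 CPM in HF and 1720.03 ± 596 in HFLF (-0.83 ± 0.25) and was the 1 member to pass when adjusted over the list alone. That pass was lost without LF replicates 1 and 4 in the fit, where 13 of 22 germ cell and 2 of 2 endothelial members passed. Next were miR-130b-5p (-0.74 ± 0.24), miR-465a-3p and miR-465b-3p (-4.25 ± 1.48 for the latter), miR-743a-3p (-4.14 ± 1.55) and miR-450b-3p (0.43 ± 0.17). The miR-200 members differed little, with miR-200b-3p at 0.06 ± 1.07 and miR-200c-3p at -0.40 ± 1.25. Here edgeR called 0 of 638, with 21 under an unadjusted p of 0.05 (19 lower) and a smallest adjusted p of 0.982. DESeq2 called 0, with 26 under that p, and limma 0, with 17. Without LF replicates 1 and 4 in the fit the macrophage list was no longer called by camera, although its median was -0.17, and the germ cell list was, with a median of -3.26 (adjusted p = 0.814 with an estimated correlation). No overlap of the comparisons against LF could be formed by edgeR, which called 0 in each. By DESeq2 they shared 15 miRNAs in eWAT, both being set against the same LF libraries, replicates 1 and 4 among them, and no value for unchanged groups was made for these lists.

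Liver and eWAT were compared within LF to describe the tissues and check their labels. Liver was far higher in miR-122-5p, at 829523 ± 84426 CPM against 675 ± 448 in eWAT under the scaling over both tissues (n = 6, log2 difference 10.26 ± 0.55). It was also higher in miR-122-3p (9.70), miR-455-3p (1838 against 119 CPM, 3.94) and miR-101b-3p (10903 against 833 CPM, 3.71 ± 0.17). Fat was higher in miR-10b-5p, which lies among the Hox genes Hoxd3 and Hoxd4 (chromosome 2, 74726070 to 74726137), at 23.5 ± 13.0 CPM in liver and 23426 ± 5552 in eWAT (-9.96 ± 0.45, adjusted p = 1.24e-19). It was also higher in miR-218-5p (10.3 against 316 CPM, -4.94), miR-127-3p (11.2 against 178, -3.99), miR-146b-5p (130 against 1452, -3.49) and miR-708-3p (0.251 against 321). The arm miR-10b-3p had no count in the 6 LF livers, with a floor of 0.0699 CPM for 3 counts, and 13166 counts in LF eWAT. By list, 12 of 14 hepatocyte members and 5 of 7 miR-29 members were higher in liver, the latter with plain CPM giving 1 higher in liver and 2 in eWAT. Higher in eWAT were 51 of 64 Dlk1-Dio3, 20 of 29 Sfmbt2, 11 of 14 fibroblast, 6 of 6 miR-34 and miR-449, 4 of 5 striated muscle and 4 of 7 miR-200 members, in a comparison that holds eWAT LF replicates 1 and 4. The adipocyte list split, with 9 members higher in liver and 11 in eWAT, against 2 and 22 under plain CPM. None of 7 erythroid members was called, against 6 higher in eWAT under plain CPM, and none of 4 miR-183 members.

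In all, edgeR called 323 of 681 miRNAs, 109 higher in liver and 214 in eWAT. Under plain CPM the split was 40 higher in liver and 422 in eWAT, and the median log2 difference over all miRNAs moved from -0.60 under TMM to -0.80 under RLE and -1.87 under plain CPM. The let-7 arms followed this shift, as let-7a-5p, let-7f-5p, let-7g-5p and let-7d-5p were higher in liver under TMM (1.07 ± 0.14, 1.03 ± 0.13, 1.11 ± 0.09 and 0.84 ± 0.15) and turned to -0.24, -0.28, -0.18 and -0.47 under plain CPM. By contrast let-7i-5p was higher in eWAT under all 3 scalings, at -0.85 ± 0.14 under TMM.

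Whether a diet group difference itself differed between the tissues was tested as an interaction. For HF against LF 17 miRNAs passed, 8 with the higher effect in liver and 9 with the higher effect in eWAT. The 8 were led by the epithelial miR-200c-3p, with a log2 effect of -0.28 in liver and -6.81 in eWAT (difference 6.53 ± 1.45, adjusted p = 0.0168). They include miR-200a-3p (5.18 ± 1.16), miR-200b-3p (5.34 ± 1.21), miR-429-3p (5.14 ± 1.18), miR-141-3p (7.68 ± 1.93), miR-205-5p (6.50 ± 1.68), miR-182-5p (3.95 ± 1.02) and miR-1247-5p (2.91 ± 0.83). Of the 9, 6 belong to the Dlk1-Dio3 cluster, with miR-127-3p at -1.12 in liver and 0.18 in eWAT (-1.30 ± 0.35, adjusted p = 0.0426). The others were miR-299a-3p, miR-668-3p, miR-376c-3p, miR-409-5p and miR-673-5p. The last 2, with miR-193b-5p, miR-708-3p and miR-708-5p, had no count in any HF liver, where the floor of 3 counts is 0.0478 CPM. In LF liver miR-409-5p (chromosome 12, 109743158 to 109743236, in an intron of the lincRNA Mirg) had 48 counts in 4 libraries, miR-673-5p 34 in 2, miR-193b-5p 16 in 3, and miR-708-3p and miR-708-5p 10 each in 2. For HFLF against LF 13 passed, 11 with the higher effect in liver. These were miR-200c-3p (7.07 ± 1.47, adjusted p = 0.0082), miR-375-3p (7.19 ± 1.60), miR-429-3p, miR-200a-3p, miR-200b-3p, miR-200b-5p, miR-141-3p, miR-182-5p, miR-183-5p, miR-96-5p and miR-205-5p. The other 2 were miR-708-3p and miR-708-5p, again at 0 in HFLF liver (floor 0.0579 CPM). For HFLF against HF 0 of 681 passed by edgeR, with 58 under an unadjusted p of 0.05, and 1 by DESeq2, miR-409-5p.

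Naming all 17 and 13 went beyond the fixed rule and was chosen after their values were seen. With libraries of the same group and number taken as 1 mouse, edgeR called 0 for HF against LF, with 19 under an unadjusted p of 0.05, and 0 for HFLF against LF, with 21. Without eWAT LF replicates 1 and 4 edgeR called 0 for HF against LF, with 78 under an unadjusted p of 0.05, and 0 for HFLF against LF, with 62. The 8 and 11 with the higher effect in liver then had median differences of 0.39 (5.26 with the pair) and 0.99 (5.71), with miR-200c-3p at 0.29 and 0.83, miR-375-3p at 2.68 and miR-1247-5p at 2.04. The 9 and 2 with the higher effect in eWAT then had fitted medians of -4.72 (-4.92 with the pair) and -5.08 (-5.34). All 11 were under an unadjusted p of 0.05. The median for HF against LF is the fit of miR-708-5p, and that for HFLF against LF is over the miR-708 arms alone. These arms had no count in the HF or HFLF liver group. Their fits rest on the prior count, so these medians give no exact size. Not among the miRNAs with no count was miR-127-3p, at -1.32 ± 0.38. Of HF against LF, 4 calls were left without eWAT LF replicate 4, 5 without liver HF 2 or any of eWAT HF 2, 3, 4 and 6 (miR-200a-3p, miR-200b-3p, miR-200c-3p, miR-429-3p and miR-409-5p). There were 6 without liver LF 1, liver LF 2 or eWAT HF 5, 7 without liver HF 3, 8 without liver HF 1, liver HF 6 or eWAT LF 1, 10 without liver HF 4, and 11 without liver LF 5 or eWAT LF 3. Of HFLF against LF, 5 were left without eWAT LF 4, 6 without eWAT LF 1, and 8 without liver HFLF 6 or eWAT HFLF 2. Without eWAT LF 4 alone the 4 were miR-200a-3p, miR-200b-3p, miR-429-3p and miR-409-5p, and the 5 were miR-200a-3p, miR-200b-3p, miR-200c-3p, miR-429-3p and miR-375-3p. DESeq2 called 29 and 21.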

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

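Chosen after the result was seen were the tests of epithelium, carry-over and the LF group for the miR-200 family, the tests of mixed tissue and of the shared shift for liver (the former in place of an earlier version on scaled values), the tests of the pair and of the smaller group for the interactions, and the splits for comparisons with 0 calls. The other tests were written before their results were seen. Several measures of the same groups of 6 libraries gave 150 sets of 6 values. In 31 sets a library stood apart from the rest of its group. Chance gives about 1 in 20 sets, or 7.5, but the sets share libraries and list members, so they are not independent. Of the 31, liver HF replicate 6 accounted for 8, liver LF replicate 4 for 7 and eWAT LF replicate 1 for 3.

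The miR-200 family reached 16656 and 21371 CPM in eWAT LF replicates 1 and 4, against 59.5 to 290.3 in the other 16 eWAT libraries. Reads carried over from another of the 36 libraries are argued against. The highest of the other 34 held 1128 CPM and the lower of this pair 11299, both scaled over all 36 libraries. Carry-over from libraries outside these 36 could not be tested. Without the pair the family's median log2 difference between HF and LF was -0.36 (SD over members 0.82, from -1.26 to 0.98), against -5.26 with it. The pair was left out for its high values, so this cannot decide on a difference of the LF group as a whole. The other LF libraries lay among the 16 at 59.5 to 290.3 CPM, so the high level was not shared by all of LF. Epithelial tissue next to the fat pad is a candidate explanation, as the miR-183-96-182 cluster was also higher in both libraries of the pair, at 602 and 3352 CPM, than in any other eWAT library. Replicate 1 also held 4615 CPM of the germ cell and epididymis list (49.3 to 1462 in the other LF libraries), 3878 CPM of the pancreas list (316 to 748), and 4748 CPM of miR-34 and miR-449 (248 to 471).

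Liver LF replicate 4 and HF replicate 6 had 316 and 368 miRNAs with a count (563 to 624 and 540 to 628 in the others of their groups) and let-7 sums of 381183 and 342657 CPM (149005 to 198143 and 148242 to 192613). Lower depth is excluded, since the other liver libraries thinned to 8496919 counts still showed at least 540 miRNAs, and so is eWAT mixed in, since their let-7 would need miR-122-5p at 9.60% of counts and the lower of them held 51.5%. Few starting molecules may account for the missing miRNAs, because 58.9% and 49.2% of the 185 miRNAs of 1 to 10 CPM were at 0 (1.08% to 8.65% in the others) while their summed CPM stayed at 0.794 and 0.929 of the median. Chance loss of molecules does not give the shift that both libraries shared over 148 abundant miRNAs (across miRNAs, which are not independent, Pearson r = 0.788 and Spearman rho = 0.896), such as miR-192-5p at -2.20 and -1.50. A bias of ligation or degradation stays open and was not tested, and no biological explanation was tested, since the pair comes from different diet groups.

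The effect of HF against LF differed between liver and eWAT for 17 miRNAs and that of HFLF against LF for 13, as tested by the interaction. Both counts went to 0 without eWAT LF replicates 1 and 4. Leaving out any pair of the other 4 eWAT LF libraries gave a median of 16 calls (15 to 18) and 16.5 (13 to 23). These fits all keep replicates 1 and 4. They show that a smaller group holding this pair does not lose the calls, and cannot say what a smaller group without it gives. Calls with the higher effect in eWAT had fitted medians of -4.72 without the pair (-4.92 with it) and -5.08 (-5.34), all under an unadjusted p of 0.05. The first median is the fit of miR-708-5p, and the second is over the miR-708 arms alone. These arms were at 0 in every HF and HFLF liver. Their fits rest on the prior count, so the medians decide nothing. Not among the miRNAs at 0 were, for HF against LF, miR-127-3p at -1.32 ± 0.38 (-1.30 with the pair) and miR-299a-3p at -4.71 ± 1.35 (-4.81). The others were miR-376c-3p at -4.57 ± 1.34 (-4.41) and miR-668-3p at -3.58 ± 1.11 (-3.73). For these miRNAs the pair is argued against as the source of the fitted difference. None of them passed without it (edgeR adjusted p from 0.164 to 0.170). Liver levels of miR-299a-3p, miR-376c-3p and miR-668-3p are not given here, so their fits may also lie near the floor. The pair may carry most of the calls with the higher effect in liver, whose medians without it were 0.39 (5.26 with it, while miR-1247-5p kept 2.04 of 2.91) and 0.99 (5.71). Leaving out 1 library outside the eWAT LF group left as few as 5 of the 17 and 8 of the 13, and with libraries of the same group and number taken as 1 mouse edgeR called 0 and 0, with 19 and 21 under an unadjusted p of 0.05.

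Of 100 splits of the libraries, 3 gave as many calls as the real 17 of that interaction for HF against LF and 3 as many as the real 13 for HFLF against LF, the real ones included. Both shares are under 0.05, but the highest other splits gave 23 and 14, above the real counts. At least 1 call came from 41 and 43 of the others. Libraries were also shuffled within each tissue on their own, without the shared numbers. Chance is therefore not excluded for these interactions. For the tissue difference in LF, 1 of 100 splits, the real one, gave 323 calls and the highest other gave 150, which excludes chance. For the 7 comparisons with 0 calls all 100 splits give as many whatever the data, so these counts say nothing about chance. The highest other splits gave 6, 0 and 0 in liver (HF against LF, HFLF against LF and HFLF against HF), 4, 18 and 0 in eWAT, and 3 for the interaction of HFLF against HF.

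Other values that stood apart in liver HF replicate 6 were 82589 CPM of the adipocyte list (67770 to 72380.1 in the other HF livers), 12993.5 of the miR-29 family (5626 to 6281), 220.4 of miR-34 and miR-449 (17.2 to 49.1). It also held 4155.5 of miR-17-92 and its paralogous clusters (6506 to 7860.1), 5741 of miR-15 and miR-16 (2643 to 3182) and 131 of the Sfmbt2 cluster (22.4 to 41.8). Those of liver LF replicate 4 were 2496 CPM of the endothelial list (4441 to 5258 in the other LF livers), 11943 of the miR-29 family (5164 to 6249), 123 of miR-34 and miR-449 (30.4 to 59.8), 3552 of miR-17-92 (6859 to 8199) and 70.7 of the Sfmbt2 cluster (21.4 to 35.2). Liver HF replicate 1 held 1716 CPM of let-7 3p arms (1106 to 1273), and liver HF replicate 2 held 990.1 of the pancreas list (729 to 823). The Sfmbt2 cluster measured 45.6 CPM in liver HFLF replicate 2 (26.4 to 30.3). In eWAT, HF replicate 1 held 354720 CPM of the adipocyte list (224769 to 263283) and 314849 of the fibroblast list (196498 to 234934), the shared member being miR-143. The germ cell list measured 775 CPM in eWAT HF replicate 6 (44.1 to 250.2), and the pancreas list 319.6 in eWAT HF replicate 2 (381 to 405). HFLF replicate 6 of eWAT held 28762 CPM of the endothelial list (20905 to 23403) and 1856 of the Dlk1-Dio3 cluster (2464 to 2736), and HFLF replicate 3 held 6740.5 of miR-15 and miR-16 (7108 to 7305). LF replicate 6 of eWAT held 232526 CPM of let-7 (274251 to 287261), and LF replicate 2 held 9287 of the lymphocyte list (5225 to 6484).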

How the results depend on the processing

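Chosen after the data were seen were the fits without libraries that stood apart, each library left out of the interaction and tissue fits, and limma on the deposited log2 tables. In liver 0 miRNAs passed in all 3 comparisons by edgeR under every alternative, with any library left out, and by DESeq2 and limma (main unadjusted counts 16, 14 and 5). In eWAT HF against LF stayed at 0 and so did HFLF against HF, except that DESeq2 called 16 for the former. HFLF against LF gave 0 to 17 with 1 library left out, 7 with the stricter filter, where fewer miRNAs are tested, and 31 by DESeq2, whose overlap with HF against LF, over the same LF libraries, was 15. The cause of the DESeq2 counts was not tested. The tissue difference stayed between 290 and 462 calls, and 317 to 334 with 1 LF library left out. For HF against LF the interaction gave 29 by DESeq2 and 6 without a filter, where more miRNAs are tested, and for the others DESeq2 gave 21 and 1 (miR-409-5p). It gave 0 and 0 without eWAT LF replicates 1 and 4 (78 and 62 under an unadjusted p of 0.05), and 1 (miR-409-5p, named after its value was seen) and 0 (70 under an unadjusted p of 0.05) without these and liver LF 4 and HF 6, where the difference of miR-200b-5p turned to -0.14. With 1 library left out it ran from 4 (eWAT LF 4) to 20 (eWAT LF 5), 5 (eWAT LF 4) to 17 (eWAT HFLF 4) and 0 to 1 (miR-376c-3p without liver HF 1, miR-409-5p without liver HFLF 1 or 2). Of 23 list calls 1 held with an estimated correlation, and that list was not called by the fry test (fry adjusted p = 0.237). Without the libraries that stood apart 14 lists were called, 12 of them among the 23, and 0 with an estimated correlation as well. The let-7 totals passed no test. Their eWAT log2 difference between HFLF and LF was -0.0319 under plain CPM (the cause was not tested). With 1 library left out the liver ranges were -0.280 (without HF 6) to 0.0519 (without LF 4), -0.389 to -0.115 and -0.251 to -0.0199. Those of eWAT were -0.0308 (without LF 6) to 0.0517, -0.0792 (without LF 6) to 0.0184 and -0.106 to -0.00555. The eWAT difference between HF and LF was also negative without HF 6 (-0.0202), and that between HFLF and LF without any 1 LF library or HFLF 3, 4, 5 or 6. Over 603 values of named miRNAs and 16039 alternative values, 64 passed where the main value had not, 151 no longer passed, 1 reversed and 1322 changed sign where neither value passed, which were not counted as reversed. On simulated data with 200 miRNAs changed, changes of 1.5-fold were mostly missed, with 20.8% found in liver and 19.0% in eWAT (48.0% and 33.3% at 100 CPM or more). At 7866583 counts or more the spread between libraries far exceeded counting error, and depth was not varied in that test.

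With the replicate number as a block edgeR called 0 in all 6 comparisons within the tissues (10, 12 and 5 under an unadjusted p of 0.05 in liver, 29, 79 and 26 in eWAT). The interactions gave 0, 0 and 0 (19, 21 and 15), the tissue difference gave 290, and 22 lists were called. The median r between libraries of the same number was 0.0177 in liver (-0.542 to 0.634), against 0.0485 for other numbers. It was 0.104 in eWAT (-0.644 to 0.470), against -0.00604, and 0.0580 across tissues, against -0.0192. Across tissues 5 of 18 correlated best with their own number. Such values gave no clear sign of pairing, and a low r between different tissues cannot show that they come from different mice.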

Other observations

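The Dlk1-Dio3 cluster, a set of imprinted miRNAs on chromosome 12, was measured in both tissues. Its summed CPM in eWAT was 2328 ± 441 in LF, 2593 ± 401 in HF and 2472 ± 322 in HFLF (mean ± SD, n = 6), and in liver 95.4 ± 44.8, 56.6 ± 14.8 and 56.2 ± 25.5. Striated muscle miRNAs such as miR-1a-3p and miR-133a-3p summed to 2273 ± 1132 CPM in LF, 1586 ± 1108 in HF and 1368 ± 734 in HFLF eWAT, and to 24.4 ± 12.01, 15.7 ± 6.83 and 13.6 ± 4.67 in liver. The erythroid list held 5378 ± 1982 CPM in LF eWAT and 1771 ± 409 in LF liver, although the fit over both tissues called 0 of its 7 members (median log2 difference -0.43 between liver and eWAT). Besides, the miR-183-96-182 cluster, which was rare in most eWAT libraries, held 394 ± 147 CPM in LF liver. These sums are scaled within each tissue, so their sizes cannot be compared between tissues, and no test was run on them.

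The authors' liver log2 table leaves out LF replicate 4 and HF replicate 6, the liver libraries with the fewest miRNAs and the highest let-7 shares, while both eWAT libraries high in the miR-200 family are kept in theirs.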
